A study of Mus musculus with 6 samples.

How the data were processed

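RNA was measured in 6 samples of the left ventricle of wild-type mice, 3 after a sham operation and 3 after transverse aortic coarctation, 5 weeks after surgery. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was purified with oligo(dT) beads and fragmented, and libraries were made by a method that marks the second strand with dUTP. Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d and the genome build was GRCm38; the annotation release, filters and whether counting used strand are not given in the sources used here. The file headers give each library its own columns, but the labels do not state that each sample came from a separate mouse.

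The authors deposited FPKM and estimated counts for 24602 genes, per the file headers. How the count columns were made is not given in the sources used here. Among single-transcript genes under 60 counts, between 88.6% and 90.1% of the deposited estimated counts per library equalled FPKM times length times a library factor, rounded up, within 0.1. They were therefore treated as estimates derived from coverage and not as tallies of reads. They were already whole numbers. Counting error understates their uncertainty, because fragments are divided between overlapping records.

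Samples were grouped by their labels. The plan fixed before the data were examined was limma for FPKM, with edgeR's quasi-likelihood test as the main test if raw counts were present. The counts present are estimates and not raw counts, so the plan did not strictly cover them. The choice of edgeR was made with the data at hand, and limma on log2(FPKM + 1) became an alternative. Genes with a mean FPKM of 1 or more over the 6 libraries were kept, which left 8795. Libraries were scaled by TMM, dispersions were estimated with estimateDisp, and groups were compared with glmQLFit and glmQLFTest (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment over all tested genes. The standard error of a log2 fold change is its size divided by the square root of the F statistic, an approximation. CPM are counts scaled by TMM library size, given as mean ± SD.

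Gene lists (30 programmes and 23 sets of cell type markers) were fixed before the data were examined and were tested together with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, where at least 3 genes were tested, with adjustment over lists. Camera was also run with an estimated correlation, under which no list passed, and fry, a rotation test of whether the genes of a list move 1 way on balance, passed 2 lists, the pressure-overload and skeletal muscle genes. Annotation terms (GO, KEGG and Reactome) in the deposited table with 10 to 500 tested genes were tested against the 7988 tested genes with an annotation.

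Genes were named by a rule fixed before the data were examined: a panel of heart failure genes whatever their result; the 10 largest rises and 10 largest falls among called genes with a mean FPKM of 2 or more, groups that did not overlap and a proper symbol; and, for each list, up to 4 called members with the lowest adjusted p, or up to 2 members with the highest mean FPKM where none was called. The rule named 127 genes, of which 91 were called; the text gives the values of those that matter most.

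GC content, transcript length and overlap between records came from GENCODE M21 for GRCm38, in which 24547 of the identifiers were found and 21895 had the same coordinates. To remove trends, each library's deviation from the mean log2 CPM was smoothed over GC content and length by lowess (span 0.3, 3 rounds) and passed to edgeR as offsets. Other alternatives were DESeq2 1.42.0, other scalings, filters, pseudocounts of 0.1 and 0.5 within limma, quantile normalization, library quality weights, a variance prior without a trend, the replicate number as a block, an atrial score as a covariate, merged overlapping records, and leaving out each library in turn.

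The tests were checked on simulated counts for the 8795 genes with the real means, library sizes and dispersions, with 200 genes changed. For the comparison of sham and TAC, edgeR recovered 50.0% of 100 genes changed 2-fold and 97.0% of 100 changed 4-fold, and 8 of its 155 calls were unchanged genes. With the libraries' own GC and length trends added, 39 of 177 calls were unchanged genes, and 11 of 162 once the trends were removed. The trends were added and removed by the same smoothing. That drop was therefore built in and does not show how the removal acts on trends of another form. DESeq2 called 32 unchanged genes among 198 without a trend.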

Results

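Poly(A)-selected RNA of the mouse left ventricle was sequenced 5 weeks after transverse aortic coarctation (TAC) or a sham operation. A narrowed aorta loads the left ventricle with pressure. There were 6 libraries, 3 sham and 3 TAC, all from wild-type mice. The deposited estimated counts summed to between 64023153 and 69992502 per library. Of the 24602 genes in the table, 8795 had a mean FPKM of 1 or more and were tested. The labels number the samples within each group and do not state that each came from a separate mouse, so the p-values measure only the spread between these samples, which may be technical.

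The comparison asked which genes differ between the pressure-loaded and the sham-operated left ventricle. Of 14 tested pressure-overload marker genes 8 rose in TAC and 6 did not pass. Nppb, which encodes B-type natriuretic peptide, went from 115.6 ± 16.1 to 345 ± 43.3 CPM, and Acta1, skeletal alpha-actin, from 453 ± 213 to 3600 ± 1085 CPM (SD, n = 3 each). Matrix and fibroblast genes such as Postn, which encodes periostin, Ltbp2 and Thbs4 rose as well, whereas the fibrillar collagens Col1a1 and Col3a1 did not pass the test. Among the genes that fell were the potassium channel subunit Kcne1, the alpha-1B adrenergic receptor Adra1b and citrate synthase, Cs. In edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 414 genes were higher and 201 lower in TAC, and 250 of these changed at least 2-fold (193 higher, 57 lower).

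**Figure D1:**
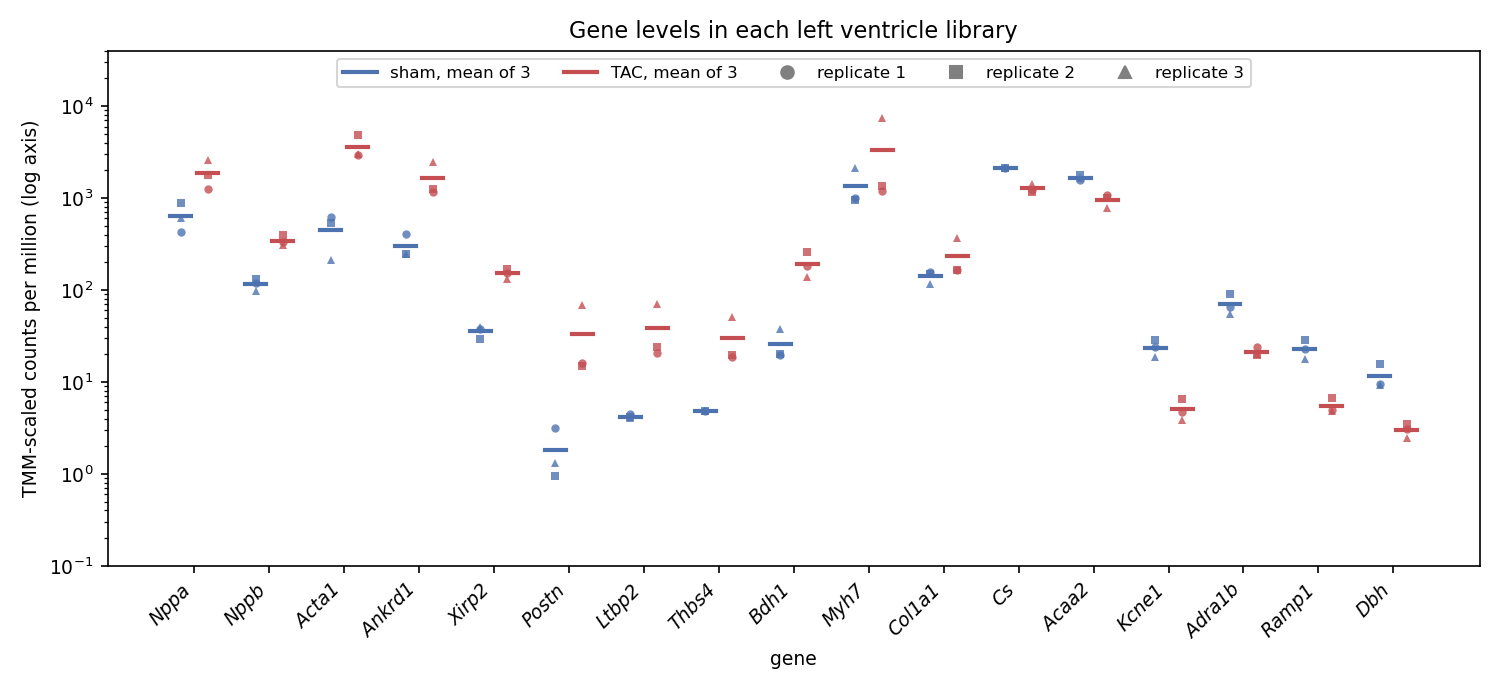
Levels of named genes in each library, as CPM on a log axis; points are the 6 libraries, with the replicate number as the symbol, and bars are group means (n = 3). Postn, Ltbp2, Thbs4 and Myh7 were highest in TAC replicate 3, where Myh7 reached 7435 CPM against 1206 and 1357 CPM in TAC replicates 1 and 2.

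The largest rises among genes with separate groups included Sprr1a, a small proline-rich protein gene with 0, 0 and 8 estimated counts in the sham libraries and 68, 103 and 1017 in the TAC libraries (log2 fold change 7.11 ± 1.42, SE; edgeR adjusted p = 0.0314). Ltbp2, a latent TGF-beta binding protein, rose by 3.19 ± 0.46, Acta1 by 2.99 ± 0.41 and Bdh1, the mitochondrial enzyme that interconverts ketone bodies, by 2.91 ± 0.32 on the log2 scale. The water channel gene Aqp8 rose by 2.84 ± 0.20 and the matrix gene Cilp by 2.77 ± 0.48. The stress cytokine gene Gdf15 rose by 2.68 ± 0.53, the carboxypeptidase-like Cpxm2 by 2.64 ± 0.27 and thrombospondin 4, Thbs4, by 2.63 ± 0.39. Without TAC replicate 3 the log2 fold change was 5.09 for Sprr1a, 3.11 for Postn, 2.42 for Ltbp2, 1.99 for Cilp and 1.99 for Thbs4, and all 5 still passed. All 91 named and called genes stayed called in that fit, against 8 of 91 without sham replicate 2. None of the 5 was among the 11 genes called whichever library was left out.

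The largest falls with separate groups included Afmid (log2 fold change -2.31 ± 0.28), an arylformamidase of tryptophan breakdown with 44.2% of its exonic bases inside another record on the same strand, so that its counts are uncertain. Kcne1 on chromosome 16 (92345982 to 92359468 in GRCm38) fell from 23.6 ± 4.96 to 5.04 ± 1.40 CPM (log2 fold change -2.23 ± 0.25, edgeR adjusted p = 0.00989). Ramp1, a receptor activity-modifying protein, had a log2 fold change of -2.05 ± 0.23 and the kinase gene Sbk2 of -1.99 ± 0.32. Dbh, which encodes the enzyme that makes noradrenaline, and Sorcs2 had -1.92 ± 0.27 and -1.92 ± 0.31. The dopamine receptor gene Drd2 (-1.81 ± 0.28), Adra1b (-1.72 ± 0.20) and the sulfotransferase gene Gal3st3 (-1.65 ± 0.23) also fell. Nnt, nicotinamide nucleotide transhydrogenase, had 2 overlapping records on chromosome 13. The record named by its size held 38282, 15896 and 5229 estimated counts in sham and 1, 0 and 0 in TAC. The other held 1561, 17972 and 16088 in sham and 22754, 19377 and 51919 in TAC. Added together, the Nnt records came to 463.5 ± 129 CPM in sham and 477 ± 222 CPM in TAC. That difference is smaller than the spread between replicates, so the counts of either record alone are uncertain.

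Of the 14 tested pressure-overload marker genes, 8 rose, none fell and 6 did not pass (9 rose adjusted over the list alone), with a median log2 fold change of 1.29. Besides Nppb and Acta1, these were led by Xirp2, a muscle actin-binding protein gene that went from 35.6 ± 5.43 to 152 ± 18.1 CPM (log2 fold change 2.09 ± 0.17, edgeR adjusted p = 0.00227), and Enah, an actin regulator (2.09 ± 0.23, adjusted p = 0.00938). Ankrd1, a titin-bound stress protein gene, rose by 2.45 ± 0.34, and Nppa, the atrial natriuretic peptide gene, by 1.54 ± 0.33, from 639 ± 230 to 1863 ± 670 CPM (adjusted p = 0.0352). Of the exonic bases of Nppa, 61.5% overlap a record on the other strand, and whether the counting used strand is not given in the sources used here. Myh7, the beta-myosin heavy chain gene, measured 1362 ± 677.5 CPM in sham and 3333 ± 3553 CPM in TAC (adjusted p = 0.262). Myh6, the alpha chain, measured 29928 ± 3922 and 21636 ± 4433 CPM (log2 fold change -0.47 ± 0.21, adjusted p = 0.189). The calcium pump gene Atp2a2 (-0.22 ± 0.25) and Ppargc1a (0.87 ± 0.28) did not pass either, with adjusted p of 0.608 and 0.0888, nor did Ccn2 at 59.2 ± 18.9 and 118 ± 98.2 CPM (adjusted p = 0.254). This list stood above other genes by camera with a preset correlation (adjusted p = 3.66e-14), and its adjusted p was 0.0860 with an estimated correlation. Its median was 0.82 without TAC replicate 3.

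Of 30 non-collagen matrix and matricellular genes, 12 rose, none fell and 18 did not pass (19 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.92. Postn rose by 4.20 ± 0.72, from 1.80 ± 1.16 to 33.3 ± 30.6 CPM, the small proteoglycan gene Aspn by 2.42 ± 0.37 and the microfibril gene Mfap5 by 1.39 ± 0.22. Among 11 activated fibroblast markers 6 rose and none fell (8 rose adjusted over the list alone; median 1.26). Among 13 resting fibroblast markers 4 rose and none fell (5 rose and 1 fell adjusted over the list alone; median 0.73). They were Mfap5 and Dcn, which encodes decorin (1.31 ± 0.27), Lum (1.55 ± 0.35) and Pi16 (0.67 ± 0.15). The cross-linking and turnover enzymes had 2 risen genes of 20 (3 adjusted over the list alone; median 0.53). These were the protease inhibitor gene Timp1 (2.02 ± 0.24) and the collagen prolyl hydroxylase gene P4ha1 (1.10 ± 0.21). The TGF-beta list had 2 of 14, Ltbp2 and Gdf15 (2 adjusted over the list alone; median 0.53). These lists share risen genes, so their counts and camera values are not separate lines of evidence. Postn, Cilp, Comp, Thbs4, Mfap4 and Ltbp2 are on both the activated fibroblast and the non-collagen matrix lists. Mfap5, Dcn and Lum are on both the resting fibroblast and the non-collagen matrix lists. None of 16 collagens passed, over all genes or adjusted over the list alone (median 0.18, camera adjusted p = 0.473). Col1a1 measured 141 ± 21.5 and 234 ± 118 CPM (adjusted p = 0.173), Col3a1 153 ± 51.5 and 280.0 ± 232 CPM (adjusted p = 0.310). The basement-membrane genes Col4a1 and Col4a2 had log2 fold changes of 0.06 ± 0.23 and -0.18 ± 0.22. The camera adjusted p was 9.93e-11 for non-collagen matrix, 5.25e-07 for activated and 0.00844 for resting fibroblast markers. It was 0.00222 for cross-linking enzymes and 0.0139 for the TGF-beta list. With an estimated correlation the adjusted p was 0.645 for resting fibroblast markers and 0.456 for each of the other lists. TAC replicate 3 stood apart in these genes, at 68.5 CPM of Postn against 16.2 and 15.1 in TAC replicates 1 and 2, and 548 CPM of Col3a1 against 139.5 and 153. Without that library the medians were 0.55 for non-collagen matrix, 0.23 for resting fibroblast markers and 1.07 for activated fibroblast markers. They were 0.23 for cross-linking enzymes, 0.22 for the TGF-beta list and -0.08 for the collagens. The call of the resting fibroblast markers was then lost (camera adjusted p = 0.0614).

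Of 30 fatty acid uptake and oxidation genes, 5 fell, 1 rose and 24 did not pass (10 fell and 4 rose adjusted over the list alone; median -0.22, camera adjusted p = 0.0760). The fatty acid transporter gene Slc27a1 fell (log2 fold change -0.90 ± 0.17), as did the thiolase Acaa2 (-0.82 ± 0.16) and the carnitine carrier Slc25a20 (-0.66 ± 0.13), and the fatty acid receptor Cd36 rose (1.22 ± 0.23). Of 18 tricarboxylic acid cycle genes, 2 fell and 2 rose (5 fell and 2 rose adjusted over the list alone; median -0.26). Cs went from 2116 ± 10.2 to 1276 ± 142 CPM (log2 fold change -0.73 ± 0.14, edgeR adjusted p = 0.0314). Dlst had -0.61 ± 0.13, against 0.65 ± 0.15 for Dld and 0.92 ± 0.22 for Sucla2. The list lay below other genes by camera (adjusted p = 0.0427), with adjusted p = 0.456 with an estimated correlation. This call was lost in 5 of 6 fits without 1 library (0.103 and 0.118 without sham replicates 1 and 3, 0.0605, 0.0894 and 0.0510 without TAC replicates 1, 2 and 3). With the GC and length trends removed, Cd36, Dld and Sucla2 did not pass (adjusted p of 0.0639, 0.730 and 0.147). In glycolysis, the phosphofructokinase gene Pfkm (-0.70 ± 0.13) and the insulin-responsive glucose transporter gene Slc2a4 (-0.57 ± 0.13) fell among 20 genes (4 fell adjusted over the list alone; camera adjusted p = 0.182). Of 20 branched-chain amino acid and ketone genes, Bdh1 and Hibch (1.53 ± 0.30) rose and 18 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.741).

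Of 13 mitochondrially encoded mRNAs, mt-Atp6, mt-Atp8 and mt-Co2 rose and 10 did not pass (12 rose adjusted over the list alone), with a median log2 fold change of 0.94. The camera adjusted p was 1.19e-07 and the adjusted p 0.456 with an estimated correlation. These mRNAs are poor in G and C (median 37.1%), and their median was 0.05, with a camera adjusted p of 0.750, once each library's trends over GC content and length were removed. Genes of the mitochondrial chromosome took 16.9 ± 2.23% of all estimated counts in sham and 26.3 ± 3.37% in TAC (SD, n = 3 each), all 3 TAC libraries above all 3 sham libraries. An exact 2-sided permutation test of 3 against 3 cannot go below p = 0.1. Their near-identical copies on chromosome 1 took 3.89 ± 0.346% and 5.98 ± 0.803%, and reads shared with those copies make both values uncertain. Of 66 nuclear-encoded respiratory chain genes, 4 rose and 62 did not pass (4 rose adjusted over the list alone; median -0.01, mean 0.04, camera adjusted p = 0.974). The 4 were Uqcrb (0.86 ± 0.18), Ndufa5 (0.86 ± 0.19), Ndufa1 (0.88 ± 0.20) and Cox7b (0.60 ± 0.14). With the trends removed, Uqcrb had a log2 fold change of 0.06, Ndufa1 of 0.53 and Cox7b of -0.03, and 1 of the list's genes rose and 1 fell. The list lay above other genes without TAC replicate 3 (camera adjusted p = 0.00206). With all libraries and the trends removed it lay below them instead (median -0.15, camera adjusted p = 0.0205). With all libraries and an estimated correlation the camera adjusted p was 0.990, and 0.790 with the trends removed.

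Potassium channel genes were among those that fell. Of 18 potassium and sodium channel genes, 5 fell, none rose and 13 did not pass (10 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.57. Besides Kcne1, Kcnip2, a subunit of the transient outward current, had -0.65 ± 0.13, Kcnq1 -0.87 ± 0.18 and Kcnh2 -0.81 ± 0.17 (edgeR adjusted p of 0.0323, 0.0341 and 0.0358). The camera adjusted p was 3.08e-05, and the adjusted p 0.456 with an estimated correlation. With the GC and length trends removed the median was -0.36 and 1 gene fell and 1 rose. Kcnip2, Kcnq1 and Kcnh2 then did not pass (edgeR adjusted p of 0.0545, 0.0678 and 0.0713). The list still lay below other genes by camera (adjusted p = 0.00134, and 0.238 with an estimated correlation). Of 20 calcium handling genes, the T-type calcium channel genes Cacna1g (-1.15 ± 0.20) and Cacna1h (-1.39 ± 0.31) fell and 18 did not pass (2 fell adjusted over the list alone; median 0.14, mean -0.03, camera adjusted p = 0.905). Cacna1g was also the fallen gene among 4 conduction system markers (3 fell adjusted over the list alone; median -0.90, camera adjusted p = 0.00319, adjusted p = 0.456 with an estimated correlation). In the renin-angiotensin and adrenergic list of 13, Adra1b fell from 69.9 ± 18.3 to 21.2 ± 2.31 CPM. The angiotensin-converting enzyme gene Ace (0.79 ± 0.16) and the receptor kinase gene Grk5 (0.92 ± 0.19) rose (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.328).

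Of 25 sarcomere and Z-disc genes, 3 rose and 22 did not pass (3 adjusted over the list alone; median 0.26). They were the Z-disc protein genes Myot, from 6.18 ± 1.81 to 36.4 ± 4.89 CPM (log2 fold change 2.56 ± 0.24, edgeR adjusted p = 0.00623), Pdlim5 (1.38 ± 0.22) and Nexn (1.42 ± 0.29). In the cytoskeleton list Tmsb4x (0.74 ± 0.12), the vimentin gene Vim (0.79 ± 0.15) and the integrin gene Itgb1 (0.98 ± 0.22) rose among 24 (3 adjusted over the list alone; median -0.02, mean 0.12, camera adjusted p = 0.466). Of 23 unfolded protein response and chaperone genes 3 rose, Dnajc3 (1.26 ± 0.22), Pdia3 (0.93 ± 0.19) and Hsp90b1 (1.35 ± 0.29). There were 5 adjusted over the list alone and a median of 0.40. Of 21 oxidative stress genes the metallothionein gene Mt2 (1.75 ± 0.34) and the peroxidase gene Gpx3 (from 358 ± 80.9 to 717 ± 187 CPM) rose (5 adjusted over the list alone; median 0.36). Of the exonic bases of Mt2, 73.5% overlap a record on the other strand. Bnip3 (1.33 ± 0.28) and the cathepsin gene Ctsl (0.78 ± 0.17) were among 4 risen autophagy and lysosome genes of 26 (7 rose and 1 fell adjusted over the list alone; median 0.34). Of 15 complement genes 1 rose and 14 did not pass (3 rose adjusted over the list alone; median 0.31). The camera adjusted p was 0.0446 for the sarcomere, 0.00446 each for chaperones and oxidative stress, 0.0224 for autophagy and lysosome and 0.0151 for complement. With an estimated correlation the adjusted p was 0.722 for autophagy and lysosome and 0.456 for each of the other 4 lists. The sarcomere median was 0.07 without TAC replicate 2 (camera adjusted p = 0.129) and the call was also lost without sham replicate 1 (0.0712). With the GC and length trends removed the sarcomere median was 0.06 and the list still passed (0.00666, but 0.445 with an estimated correlation). The autophagy and lysosome median was 0.21 without TAC replicate 3 (0.246), and the call was also lost without sham replicate 1. With the trends removed the median was 0.17 and the list still passed (0.0315, but 0.6105 with an estimated correlation). The call of complement was lost without sham replicate 1 (0.123).

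Markers of other cell types were counted in the same way. None of 14 ventricular cardiomyocyte markers passed, over all genes or adjusted over the list alone (median -0.06, camera adjusted p = 0.890). Of 11 atrial markers Nppa rose (3 rose and 2 fell adjusted over the list alone; median -0.43, adjusted p = 0.974). Single members rose among 16 endothelial markers (Tek, 0.70 ± 0.17; median 0.23, camera adjusted p = 0.202) and 10 pericyte markers (Rgs5, 1.05 ± 0.19; median -0.10, mean 0.13, adjusted p = 0.905), each with 1 adjusted over the list alone. The same held for 9 smooth muscle markers (Cnn1, 1.68 ± 0.28; median 0.26, adjusted p = 0.217) and 11 macrophage markers (Lgals3, 1.23 ± 0.30; median 0.06, adjusted p = 0.669), with 1 and 2 adjusted over the list alone. None passed among 6 lymphatic (median 0.45, camera adjusted p = 0.123; 3 rose adjusted over the list alone) or 4 dendritic markers (median -0.07, adjusted p = 0.741; 0 adjusted over the list alone). Nor did any of 3 adipocyte markers (median 0.04, adjusted p = 0.669; 1 rose adjusted over the list alone). The 6 red blood cell markers had a median of 0.98 and none passed singly or adjusted over the list alone (camera adjusted p = 0.0224, adjusted p = 0.652 with an estimated correlation). Their median was 0.65 without sham replicate 2 and 1.51 without sham replicate 3, and the call was lost without sham replicate 1 or 2 or TAC replicate 1 or 2 (camera adjusted p of 0.0916, 0.0681, 0.0644 and 0.0894). The 4 tested skeletal muscle markers included Acta1, Myl1 (1.61 ± 0.26) and Mybpc2 (1.28 ± 0.29), which rose (3 adjusted over the list alone; camera adjusted p = 0.000510, adjusted p = 0.350 with an estimated correlation). Acta1 and Mybpc2 also belong to the pressure-overload list. Of 5 cartilage and valve markers Prg4, which encodes lubricin (1.74 ± 0.16), and Comp (1.60 ± 0.32) rose (2 adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.456 with an estimated correlation). The median of the list went from 1.002 to -0.02 without TAC replicate 3 (camera adjusted p = 0.0671), and the call was also lost without sham replicate 1 (0.119).

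Too few members were measured for a test of neutrophil, B cell, Schwann cell and neuron, mast cell, epicardial, platelet and sex-linked markers. Their medians were 0.24, 0.58 and -0.57 over 2 genes each, and 0.79, 1.86, -0.02 and 0.64 for the single genes Mcpt4, Krt18, Pf4 and Ddx3y. Dbh fell among them, and none of the others passed over all genes. Adjusted over the list alone, 1 mast cell, 1 epicardial, 1 sex-linked and 1 Schwann cell and neuron marker rose and Dbh of the last list fell. For a list with 1 tested gene this is the unadjusted p. With the GC and length trends removed the log2 fold changes were 0.625 for Mcpt4, 2.07 for Krt18 and -0.11 for Ddx3y. No T or natural killer cell marker reached the expression minimum.

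Among the remaining programmes, Cp, which encodes the ferroxidase ceruloplasmin (1.88 ± 0.26), and Ncoa4 (0.94 ± 0.22) rose in the ferroptosis and iron list of 15 (3 rose and 2 fell adjusted over the list alone; median -0.11, mean 0.07, camera adjusted p = 0.921). Alox5 (-1.04 ± 0.21) and Lpcat3 (-0.57 ± 0.14) fell. Tnfrsf12a (1.58 ± 0.33), a receptor of the tumour necrosis factor family, rose in the apoptosis list of 10 (1 adjusted over the list alone; median -0.03, mean 0.09, adjusted p = 0.974). Gdf15 rose among 12 mitochondrial stress genes (3 rose and 1 fell adjusted over the list alone; median 0.27, adjusted p = 0.234) and Tek among 16 angiogenesis genes (1 adjusted over the list alone; median 0.07, adjusted p = 0.487). Of 40 ribosomal protein genes 4 rose, led by Rps24 (0.87 ± 0.15) and Rpl23 (0.94 ± 0.17; 5 adjusted over the list alone; median 0.07, camera adjusted p = 0.154). None passed, over all genes or adjusted over the list alone, among 5 cell cycle genes (median 0.47, camera adjusted p = 0.541) and 10 chemokine and adhesion genes (median 0.31, 0.102). The same held for 19 interferon genes (median 0.05, 0.667), 15 immediate early genes (median 0.22, 0.350) and 13 circadian genes (median 0.03, 0.905).

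Besides the respiratory chain, 8 lists that did not pass did so when 1 library was left out. Without TAC replicate 3 these were endothelial markers (median 0.45, camera adjusted p = 0.000157), ribosomal proteins (0.22, 0.00113), chemokine and adhesion genes (0.51, 0.0196) and mitochondrial stress genes (0.31, 0.0399), all up. Fatty acid genes (-0.27, 0.0399) and renin-angiotensin and adrenergic genes (-0.33, 0.0399) passed there as down. Immediate early genes passed without TAC replicate 1 (0.43, 0.00619) and lymphatic markers without TAC replicate 2 (0.62, 0.0431). Ribosomal proteins passed also without sham replicate 3 (0.18, 0.0165), and without sham replicate 2 so did chemokine and adhesion genes (0.29, 0.0279) and fatty acid genes (-0.32, 0.0249). All these calls are at the preset correlation, and with all libraries and an estimated correlation 0 lists passed.

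**Figure D2:**
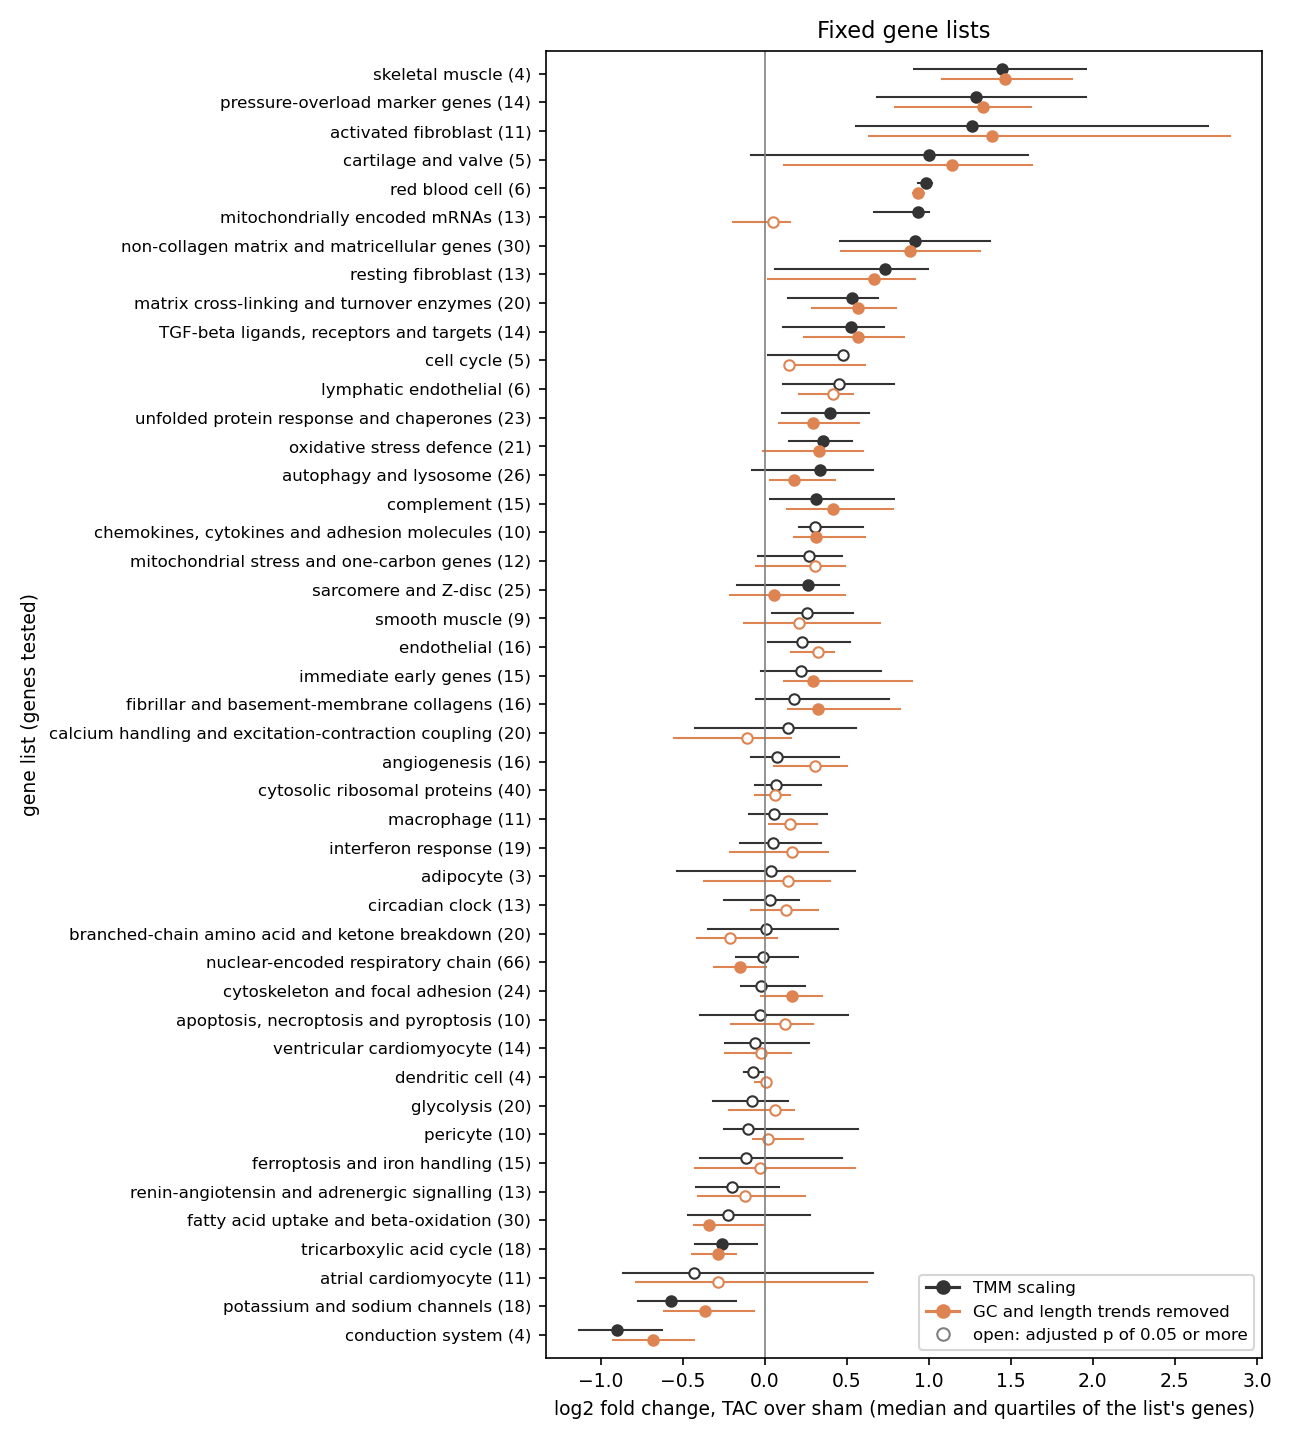
Median log2 fold change of TAC over sham (point) with the quartiles (line) for each fixed list with at least 3 tested genes, with TMM scaling and with the libraries' GC and length trends removed; filled points passed camera at a preset correlation. The pressure-overload list lies at 1.29 and 1.33, and the mitochondrially encoded mRNAs at 0.94 and 0.05.

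Of 3355 annotation terms, 7 were enriched among the higher genes and 5 among the lower genes by a 1-sided Fisher's exact test with Benjamini-Hochberg adjustment. Genes of the extracellular region led the higher terms, with 50 called against 23.0 by chance (adjusted p = 0.000383), followed by the extracellular space (47 against 22.2, adjusted p = 0.00107). Translation initiation genes, among them Eif3a, Eif4a2 and Eif5, made up 12 calls against 2.45 (adjusted p = 0.00399) and gave 4 of the 7 terms. The apical plasma membrane gave the other (18 against 6.46, adjusted p = 0.0394). All 5 terms of the lower genes concerned ion channels and potassium transport. Voltage-gated ion channel activity held 8 calls against 0.923, among them Kcne1, Kcnh2, Kcnip2, Kcnj12, Kcnq1 and Cacna1g (adjusted p = 0.00694). With the GC and length trends removed, 13 terms passed, all of the higher genes, and shared the 2 extracellular terms. The translation and ion channel terms did not pass.

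**Figure D3:**
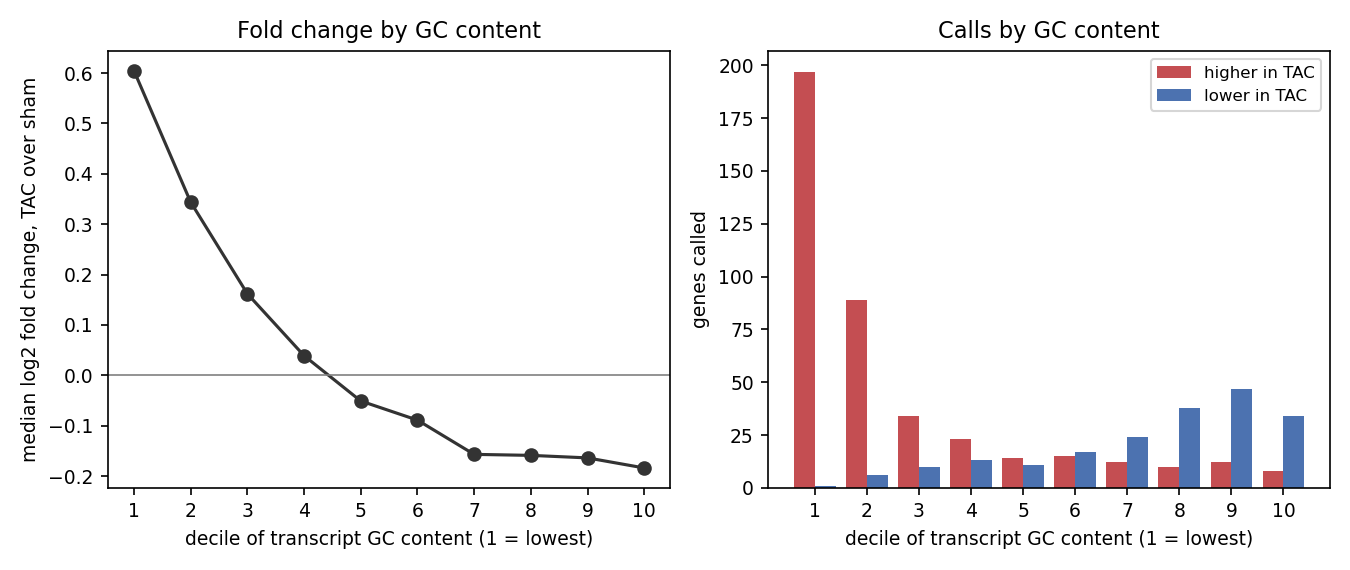
Left, median log2 fold change of TAC over sham in each decile of the tested genes by transcript GC content; right, number of genes called higher and lower in each decile. The median runs from 0.60 in the decile with the lowest GC content to -0.18 in the decile with the highest.

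Fold change moved with GC content. The Spearman correlation across genes, which are not independent replicates, was -0.49. The median GC content was 44.1% for the higher genes, 55.8% for the lower genes and 52.1% for all tested genes. With the GC and length trends removed, an alternative added after the data were seen, 243 genes were higher and 219 lower, sharing 164 and 126 with the calls above. Of the 91 genes named by rule and called, 31 then did not pass, among them Dcn, Lum, P4ha1, Slc2a4, Nexn, Tmsb4x, Hsp90b1, Bnip3, Ctsl, Ncoa4, Lpcat3, Rgs5, Lgals3, Rps24 and Rpl23. Scaling each library to a common sum, which moved the median of all genes to -0.13, gave 157 higher and 188 lower. Limma on log2(FPKM + 1), the test planned for FPKM, gave 174 and 338, with a median of -0.13. It used FPKM as deposited, with no further scaling between libraries. With quantile normalization limma gave 371 and 233, with a median of -0.04. The counts also rested on single libraries. The higher and lower genes numbered 295 and 66 without sham replicate 1, 9 and 3 without sham replicate 2, 30 and 21 without sham replicate 3. They numbered 33 and 18 without TAC replicate 1, 99 and 34 without TAC replicate 2, and 813 and 892 without TAC replicate 3. In every one of these 6 fits 11 genes were called. Among these were Xirp2, Nppb, Myot, Prg4, Aqp8 and Adra1b, the overlapping Nnt record, and Ugp2, Ccn5 and Cdv3, which were named after their values were seen.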

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

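The alternatives GC and length trends, merged records, the atrial covariate and the fits that combine these were chosen after seeing the data. Limma on log2(FPKM + 1) was the main test planned for FPKM. It became an alternative when edgeR was chosen with the data at hand. The others were planned as alternatives. The main counts were 414 higher genes, 201 lower genes, 250 changed at least 2-fold, 18 gene lists and 12 annotation terms. The higher genes fell to 174, 170 and 174 in limma with pseudocounts of 1, 0.1 and 0.5, where the lower genes rose to 338, 336 and 339 and the 2-fold genes fell to 110 and, at 0.5, to 150; quantile normalization gave 99 2-fold genes and 21 terms. Without a filter there were 163 higher and 122 lower genes and 5 terms, among 23834 genes; with a mean FPKM of 5 or more there were 143, 68, 76 and 2 terms, among 4479 genes. A common sum gave 157 higher genes and 1 term. Library quality weights gave 1343 higher, 1252 lower, 426 2-fold genes and 33 terms. They were fitted with limma on the estimated counts and not with edgeR, so the test changed along with the weights. DESeq2 gave 1031, 617, 383 and 28. With the GC trend removed there were 95, 65, 96 and 3 terms; with the length trend alone removed 681 higher, 482 lower genes and 22 terms; with the GC and length trends removed 243 higher and 137 2-fold genes; and with TAC replicate 3 left out as well 581 lower genes and 49 terms. The atrial covariate left 3, 1, 4 and 0 terms, with 1 residual degree of freedom fewer. The median log2 fold change of the higher genes went from 0.98 to 0.92 (median SE 0.20 to 0.24). That of the lower genes went from -0.81 to -0.75 (0.16 to 0.20), and 1469 genes had an unadjusted edgeR p under 0.05. The replicate block gave 141 higher, 42 lower and 161 2-fold genes and 2 terms. With the GC and length trends removed as well it gave 115, 59, 114 and 5 terms. The deviations of same-numbered samples correlated at -0.10, 0.14 and -0.06, and 1 of 3 sham libraries correlated best with its own number. These values show no clear pairing by number, but with 3 samples per group they cannot exclude it. With an estimated correlation 0 lists passed camera, and fry passed 2. Leaving out 1 library gave between 9 (sham replicate 2) and 813 (TAC replicate 3) higher genes, 3 and 892 lower genes, 12 and 386 2-fold genes, 12 and 21 lists and 0 and 39 terms. These fits of equal size ran from 12 to 1705 called genes, so the number of samples alone does not account for the differences. The nuclear-encoded respiratory chain list changed direction in 14 of 28 settings and calcium handling in 8, whether or not the list passed. Reversals of genes or lists that passed in the main fit or in the alternative came only with the GC and length trends removed. Cox7b turned to -0.027, to -0.028 with the replicate block and to -0.084 without TAC replicate 3, where mt-Atp8 and Lamp2 turned to -0.166 and -0.059. For the mitochondrially encoded mRNAs the direction of camera changed without passing (adjusted p of 0.750, 0.809 and 0.785, medians 0.05, 0.07 and -0.02) in these fits, the nuclear-encoded respiratory chain turned down at 0.0205 and, with the block, 0.0163, and calcium handling turned down at 0.0483 with the block. The cause was not tested for the other changes. Over all alternatives, named genes kept their side of the threshold in 2467 cases, lost a call in 768, gained 1 in 23 and reversed in 5. Depth was similar in all libraries, so it limits mainly genes with few counts, such as Sprr1a.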

Other observations

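The tests of the GC and length trends on the higher and lower genes and the mitochondrially encoded mRNAs, and those of depth and fibroblast share in TAC replicate 3, were chosen after the result was seen; the others were written before it, but the reading of the cardiomyocyte share test was changed, and its repeat without TAC replicate 3 added, after its result was seen.

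The report's lists came out differently with the GC and length trends removed, in both directions, and no test compared the 2 scalings. The fatty acid list lay lower (median log2 fold change -0.34, camera adjusted p = 0.000380), as did the tricarboxylic acid cycle (-0.29, 0.000122) and the nuclear-encoded respiratory chain (-0.15, 0.0205), while the collagens lay higher (0.33, 0.0134). With TAC replicate 3 left out as well the last 2 medians were -0.05 and 0.16, and neither passed (nuclear-encoded respiratory chain 0.781, fibrillar and basement-membrane collagens 0.0898). With all libraries and an estimated correlation the adjusted p was 0.0978, 0.0978, 0.790 and 0.645. Cytoskeleton (median 0.165, camera adjusted p = 0.0371), chemokine and adhesion (0.31, 0.0377) and immediate early genes (0.29, 0.0359) also passed as higher with the trends removed. With an estimated correlation their adjusted p was 0.5195, 0.479 and 0.645. In all 23 lists passed at the preset correlation, against 18 before. Glycolysis went from a median of -0.08 to 0.06 (camera adjusted p = 0.498), non-collagen matrix from 0.92 with 12 risen genes to 0.89 with 11, and the fatty acid list from 5 fallen genes to 4. The new terms among the higher genes included collagen-containing extracellular matrix, with 17 calls against 4.66 by chance (adjusted p = 0.00303), actin binding (20 against 6.47, adjusted p = 0.00322) and the Z disc (11 against 2.99, adjusted p = 0.0473), by a 1-sided Fisher's exact test.

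The first pattern is the fold change that runs with GC content. Removing the GC and length trends left the lower quartile of the 414 higher genes at 0.40 (0.83 before). The upper quartile of the 201 lower genes was then -0.51 (-0.64 before). Both sets were chosen for large fold changes in these same data, so the quartiles cannot decide whether the trends are their whole cause. Their medians shrank from 0.98 to 0.64 and from -0.81 to -0.66, and many calls ended. For the mitochondrially encoded mRNAs the lower quartile went from 0.66 to -0.19, and a trend of the libraries with GC content is a candidate explanation for their rise. Also open is whether the trend with GC content is technical or part of the response, because it separates the groups. Each library's correlation of its deviations with GC content was above 0 in sham (0.18, 0.54 and 0.32) and below 0 in TAC (-0.33, -0.20 and -0.42).

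The second pattern is the level of matrix and fibroblast genes in TAC replicate 3, where 51 genes (fibrosis genes and Myh7) exceeded TAC replicates 1 and 2 by a median of 0.91 on the log2 scale. The lower quartile of the excess was 0.35, and 0.19 with the GC and length trends removed. The median excess went from 0.91 to 0.72. The pattern was picked after the excess was seen in these same data, so these values cannot decide whether the trends are its whole cause. The deviations of TAC replicate 3 correlated with transcript length at 0.36 (Spearman), against -0.23 and -0.39 in TAC replicates 1 and 2. The total of TAC replicate 3, 69.01 M estimated counts, lay within the 64.02 to 69.99 M of the other libraries. In that sample 6 resting fibroblast markers exceeded by a median of 0.76 (SD 0.48) and collagens by 1.51. Myh7 exceeded by 2.54 against -0.17 (SD 0.65) for ventricular cardiomyocyte markers. Both gaps were larger than the SD of the markers, but they rest on 1 library and on a bound set after the excess was seen. Whether that sample held a larger share of fibroblasts of unchanged make-up is therefore not decided. Between the groups a larger share of fibroblasts stays open for the collagens, which did not pass (markers 0.73, SD 0.60, and collagens 0.82). A lower share of cardiomyocytes alone is not decided. As first computed, on the markers farthest apart (activated fibroblast and pericyte), the medians differed by 1.36, within the larger SD of 1.40. The test was recomputed after this was seen over all 15 pairs, as the written prediction named no pair. Then 2 pairs exceeded their SD, the most being resting fibroblast over pericyte at 0.83 (SD 0.65). Without TAC replicate 3 that gap was 0.29 (SD 0.56), 2 other pairs exceeded their SD (activated fibroblast over pericyte by 1.13, SD 1.08) and 0 did so in both fits, so the bound written before, which names no pair, is met each time but by pairs that depend on that library.

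The third pattern is the higher Nppa, which could come from atrial tissue in the TAC samples. The abundant atrial genes Sln, Myl7 and Myl4 had a median log2 fold change of -1.28, against 1.54 ± 0.33 (SE) for Nppa, which argues against it; Myl7 stood at 6.99, 57.6 and 41.7 CPM in sham and 42.0, 1.82 and 8.09 CPM in TAC. Atrial tissue in the sham samples stays open as a cause of the lower genes. Of 106 genes lower in the other 4 libraries, 92 were also lower in TAC replicate 1 than in sham replicate 1, which held less Myl7, with an upper quartile of -0.49, but 1 library against 1 excludes nothing. With the atrial covariate 1 of the 201 lower calls stayed. The median log2 fold change of the 201 genes went only from -0.81 (upper quartile -0.64) to -0.75 (-0.61). Their median SE rose from 0.16 to 0.20 and 1 degree of freedom was lost, so the lost calls do not speak for atrial tissue.

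Whether chance alone could group the libraries this way cannot be settled, since 3 against 3 make 10 splits and a share under 0.05 cannot be reached. The real split, 1 of the 10, gave 414 higher, 201 lower and 250 2-fold genes and 12 terms, and the highest of the others gave 0 of each by edgeR. For gene lists, 2 of the 10 splits passed 18 or more, the real one and another with 20, so the number of lists passing at the preset correlation does not set the real groups apart.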
